A study of Mus musculus with 2 samples.

How the data were processed

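Visium HD spatial gene expression was measured in 2 mouse colon sections, 1 from a control animal and 1 from an animal that had recovered from colitis. Per the labels' protocols, colitis was induced with 3 cycles of 1 to 1.5% dextran sulfate sodium (7 days on, 10 days off). Tamoxifen followed on days 21 to 23 after the last cycle at 50 mg/kg, and tissue was collected 27 days later, frozen as rolls and sectioned at 10 µm. This protocol text is the same for both samples, so the control rests on its treatment label alone. The labels name both tamoxifen and 4-hydroxytamoxifen as the inducer. The tissue label reads colonic epithelium, yet the sections hold all layers of the colon wall.

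The deposited values are UMI counts per gene and 16 µm bin, whole numbers with no normalization. They were made with Space Ranger, version 3.0.1 per the file headers, against mm10 per the submitters' processing notes. Both sections list the same 19059 genes. Gene positions come from the GRCm38.p6 gene table: 18865 genes matched by symbol, 156 by a synonym, and 38 did not match. Of 454 listed genes, 445 are in the files.

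The control section had 372214482 UMIs over 99258 deposited bins and the recovered section 290880644 UMIs over 99154. Bins under 100 UMIs were left out (2453 control, 1691 recovered), leaving 96805 and 97463. A gene at 0 UMIs in a whole section could still be present at up to 0.0081 CPM in the control and 0.0103 CPM in the recovered section, the floor of 3 counts. The most abundant gene, Muc2, took 3.03% of control and 3.47% of recovered UMIs. Across genes, log2 CPM correlated with Pearson's r of 0.984 between the 2 whole sections (genes are not independent replicates).

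A bin of 16 µm can hold several cells or parts of cells, so no cell type was assigned to bins and no doublet caller was run. A region score was the UMIs of 15 Wnt target genes (Notum, Nkd1, Nkd2, Wif1, Apcdd1, Prox1, Sp5, Lef1, Wnt6, Wnt10a, Mmp7, Rnf43, Znrf3, Axin2 and Tnfrsf19) per 10000 UMIs over a window of 5 x 5 bins. The Otsu threshold of the log2 score over both sections was 12.7 per 10000, and bins above it were called tumour-marker-high. The remaining bins above the Otsu threshold of an epithelium list (66.3 per 10000) were called other epithelium. A lesion was a connected set of at least 50 tumour-marker-high bins. Genes that define the regions are not reported as results. The regions rest on transcripts alone, as no histological annotation was used.

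UMIs were summed over each region, scaled to CPM by the region's total, and compared as the log2 ratio of recovered over control with a pseudocount of 1 CPM. Sums carry exact Poisson intervals and shares carry exact binomial (Clopper-Pearson) intervals at 95%. A sum of 100 UMIs has an interval from 81.4% to 122% of its value, and a sum of 10000 UMIs one from 98.0% to 102%. For a gene list, the median log2 ratio over members with at least 50 UMIs in both sums together is given, with its percentile among 10000 random lists matched in 20 strata of level, as a description of these 2 libraries. The median over all genes was -0.02 in tumour-marker-high regions and 0.00 in whole sections. No p-value was computed, because each group has 1 section and bins and lesions are not replicates.

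The regions, 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, in tumour-marker-high regions, the 12 highest and 12 lowest ratios among genes with at least 30 CPM in either section whose median over lesions differed in the same direction by at least 1.5-fold. Region definition and mitochondrial genes were left out there. In other epithelium it took the 8 highest and 8 lowest with the same direction in each of 4 quadrants of the recovered section. For regions against other epithelium it took the 6 highest and 6 lowest by the smaller ratio of the 2 sections. Members of the fixed lists were also named. 7 more lists were written after the named genes had been seen: glucocorticoid-responsive genes, clock genes of the Dbp and Per phase and of the Bmal1 phase, heat shock genes, cold-induced genes, and 2 lists of gastric genes. The fixed lists covered region definition, epithelium, crypt base and Wnt targets, AP-1, immediate early genes, fetal-like epithelium, proliferation, antigen presentation, type I interferon, antimicrobial epithelium, 4 mature epithelial cell types, 6 immune and 4 stromal cell types, activated stroma, hypoxia, fatty acid oxidation, posterior Hox genes, small intestine, red blood cells, the targeted locus and sex-linked genes.

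Alternatives were a score threshold 25% lower or higher, a 3 x 3 window, regions from joint clustering (15 k-means clusters on 30 components of 2000 genes, taking clusters with at least 2 definition genes among their top 10), the definition without its most abundant gene, thinning of every bin to 500 UMIs, a minimum of 300 UMIs per bin, no largest lesion, lesions of at least 200 bins, medians over lesions, TMM factors from edgeR, centring on the median gene, other count minimums and pseudocounts of 0.1 and 5, and epithelium-rich bins. Leaving out a Hoxb13-high zone (Hoxb13 above 0.25 per 10000 over 21 x 21 bins), leaving out a gastric-gene-high zone (gastric mucous genes above 10 per 10000) and pairing quadrants were chosen after seeing the data.

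The steps were tested on simulated data before use. Counts were drawn from the gene levels of both sections together at each section's depth. Of 50 genes planted with a 2-fold change 96.0% came back within 0.1 log2 units, and Poisson intervals held the drawn value for 95.4% of 18972 genes. In 12 planted discs of 20-fold higher definition genes, 99.8% of planted bins were found. They came back as 13 lesions, as 1 disc spanned a gap in the tissue, and 77.6% of the bins found had been planted, since the window widens each region by its margin.

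Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16 for TMM factors alone.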

Results

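The 2 samples were Visium HD sections of mouse colon, each from 1 Cdx2-CreERT2;APCfl/fl animal, in which tamoxifen deletes the tumour suppressor Apc in epithelium that expresses the intestinal transcription factor Cdx2. 1 animal had recovered from colitis caused by dextran sulfate sodium (DSS) before Apc was deleted, and the other is labelled control. Both colons were collected 27 days after tamoxifen and frozen as rolls, so 1 section shows a long stretch of the organ. The control section held 372214482 UMIs over 99258 bins of 16 µm, with a median of 2363 UMIs per bin, and the recovered section held 290880644 UMIs over 99154 bins, with a median of 1604. With 1 section per group there is no replicate check: every difference below is a difference between 2 libraries. Intervals of counts cover counting error only, and those of list medians are taken over genes. Intervals of shares treat bins as independent. Neighbouring bins share a score window and lie in the same lesions, so these intervals are too narrow. Gene positions are on GRCm38.

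The targeted gene was seen at like levels in both sections. In the tumour-marker-high regions Apc had 101 CPM in the recovered section and 103 CPM in the control section (log2 ratio -0.03), and Cdx2 had 412 and 386 CPM (0.09). Probes outside the deleted part of Apc would check nothing about the deletion, and the files do not give the probe positions. In both sections the 4 measured Y-linked genes were present, with a median log2 ratio of 0.17 between whole sections.

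The first comparison asked how much tumour tissue each colon held, since the series compares adenomas that formed after colitis had resolved with adenomas of control colon. Tumour-marker-high regions, called from 15 targets of the Wnt pathway that Apc restrains, took up nearly equal shares of both sections: 28.4% of bins in the recovered section (exact binomial interval 28.1 to 28.7) and 28.3% in the control section (28.02 to 28.59). Their areas were 7.09 and 7.01 mm2. The recovered section had 46 lesions and the control section had 62. The median lesion covered 0.0626 mm2 in the recovered section and 0.0429 mm2 in the control section, and the largest covered 1.71 and 0.666 mm2. That largest recovered lesion held 24.1% of the section's tumour-marker-high bins, against 9.49% for the largest control lesion.

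With every bin thinned to 500 UMIs, which left out 17773 recovered and 15189 control bins, the shares were 30.7% (30.3 to 31.0) and 29.5% (29.2 to 29.8), against 27.6% and 27.2% of the same bins unthinned. The score of 8.85% of recovered and 6.92% of control bins lay within 25% of the threshold. Regions taken from joint clustering were smaller and turned the order, with 6.99% of recovered and 10.5% of control bins. The gap in lesion number and size varied with the setting. Thinned bins gave 54 recovered and 58 control lesions with medians of 0.0490 and 0.0461 mm2, and a 3 x 3 window gave 54 and 59 lesions with medians of 0.0420 and 0.0389 mm2. Without the most abundant definition gene the medians were 0.0507 and 0.0502 mm2. With a threshold 25% lower there were 47 and 63 lesions, with joint clustering 20 and 35, and with at least 300 UMIs per bin the medians were 0.0625 and 0.0433 mm2. Among lesions of at least 200 bins the order of the medians also turned, to 0.116 mm2 for 25 recovered lesions and 0.160 mm2 for 28 control lesions. The edge of the capture area cropped 2 recovered lesions, the largest among them, and 7 control lesions.

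**Figure D1:**
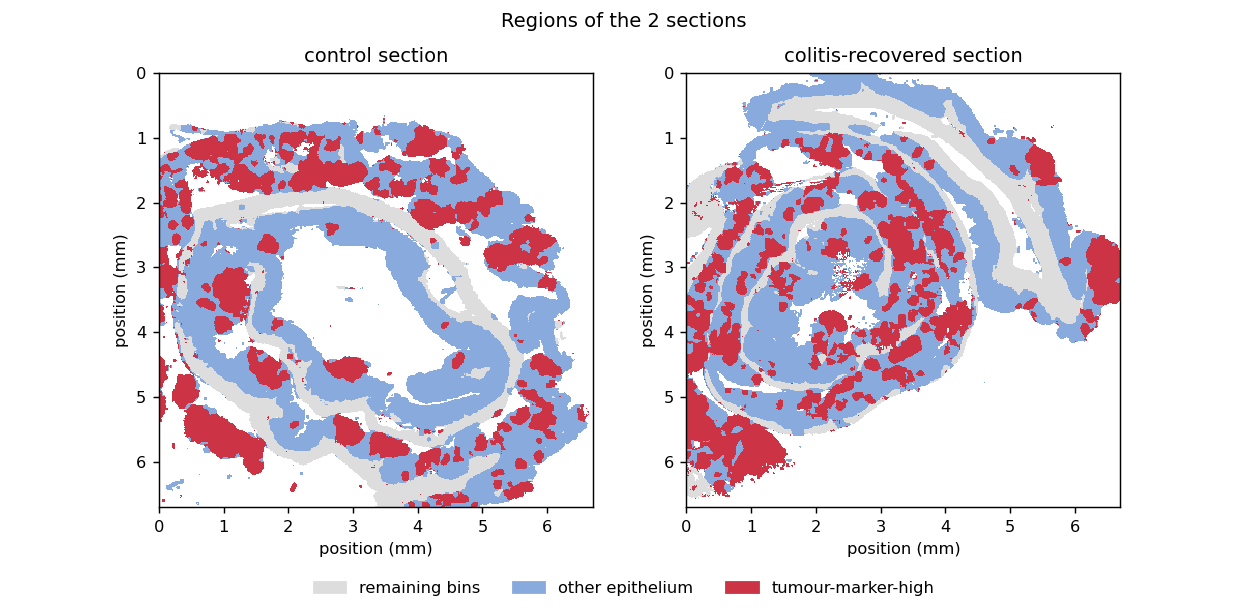
Maps of both sections with bins coloured as tumour-marker-high region, other epithelium or remaining bin; both axes are in mm. Tumour-marker-high bins are 28.4% of the recovered and 28.3% of the control section.

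**Figure D2:**
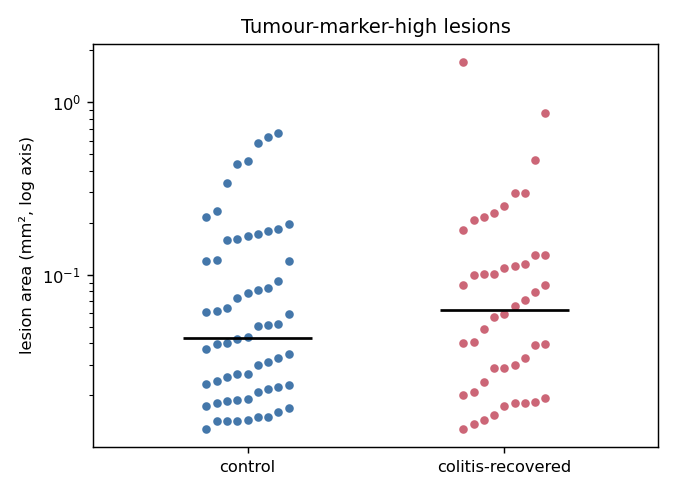
Area of each tumour-marker-high lesion in mm2 on a log axis, 1 point per lesion, with the median of each section. The 46 recovered lesions have a median of 0.0626 mm2 and the 62 control lesions 0.0429 mm2; lesions of 1 animal are not replicates.

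The second comparison asked how gene activity inside tumour-marker-high regions differed between the recovered and the control section. Cell division genes were lower in the recovered regions without exception, the hormone-responsive genes Zbtb16, Sgk1 and Fkbp5 were among the highest, and plasma cell transcripts were higher. Each of the 24 measured proliferation genes was lower, with a median log2 ratio of -0.69, or 1.61-fold lower. The mitotic genes Mki67 and Top2a had 79.6 and 119 CPM in the recovered regions against 121 and 199.6 CPM in the control regions. The replication genes Pcna (144 against 237 CPM) and Mcm2 (43.6 against 72.3 CPM) differed by about as much, and the chromatin remodeller Hells differed most (20.6 against 40.6 CPM, log2 ratio -0.94). None of 10000 random lists matched on level had a median as low, as a description of these 2 libraries. In region bins rich in epithelial and poor in other transcripts, the median was -0.40.

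Stem cell genes of the crypt base and other Wnt targets outside the region definition were also lower, 17 of 18 members, with a median log2 ratio of -0.39 (percentile 0). Ascl2, the transcription factor that maintains the stem cell state, had 47.9 CPM in the recovered and 116 CPM in the control regions. Myc had 171 and 277 CPM, Cd44 127 and 208 CPM, and Sox9 135 and 214 CPM. Lgr5, the classical stem cell marker, differed less (28.7 and 35.0 CPM), and the surface protein gene Rgmb was the 1 member that was higher (140.4 and 134 CPM).

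AP-1 transcription factor subunits had no common direction in the lesions: 6 were higher and 8 lower, with a median of -0.09 at percentile 26.4. Their summed CPM, which the abundant members set, was higher in the recovered regions (3760 against 3455 CPM), with lesion medians of 4037 and 3426 CPM. Fos (165 against 278 CPM), Fosl1 (6.02 against 15.1 CPM) and Fosb (2.57 against 7.70 CPM) were lower in the recovered regions. Jdp2 (50.8 against 27.7 CPM), Fosl2 (322 against 225 CPM) and Maff (89.9 against 67.1 CPM) were higher, and Jun was level (718 against 731 CPM). Immediate early genes, which cells switch on within minutes of a stimulus, split the same way. 8 were higher, led by Klf4 (712 against 392 CPM), and 11 lower, among them Nr4a1 (34.2 against 58.3 CPM). Their median was -0.31 (percentile 0.01), with an interval over genes of -0.46 to 0.52. Summed CPM per lesion went the other way, with medians of 3289 in the recovered and 2992 in the control section.

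Genes of fetal-like and regenerating epithelium were lower in 15 of 22 cases, with a median of -0.21 (percentile 0.5; interval over genes -0.39 to 0.08). The median was -0.01 with joint clustering and -0.03 with medians over lesions. The wound matrix gene Spp1 (1.44 against 7.73 CPM) and the alarmin Il33 (3.06 against 11.3 CPM) were the lowest, whereas Msln (10.8 against 4.30 CPM) was higher. Clu and Ly6a, often used to mark regenerating crypts, had 186 and 155 CPM against 213 and 197 CPM.

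Antigen presentation genes were higher in 19 of 22 cases when UMIs were summed over the recovered regions, with a median of 0.46 (percentile 100). The MHC class II genes Cd74 (1623 against 1150 CPM) and H2-Ab1 (842 against 609 CPM) and the class I regulator Nlrc5 (27.3 against 10.1 CPM) were among them, while the chemokine gene Cxcl10 (6.02 against 10.7 CPM) was lower. This direction rested on how lesions were weighted: with the median over lesions in place of the sum, the list stood at -0.17, and with thinned bins at 0.07. In epithelium-rich bins it was 0.90. The type I interferon list had 16 of 17 genes higher and a median of 0.35 (percentile 99.99), with Usp18 at 23.3 against 15.1 CPM. Its summed CPM per lesion was nearer level, with medians of 677 in the recovered and 635 in the control section.

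Markers of mature cells differed little. Absorptive colonocyte genes had a median of 0.21 (interval over genes -0.09 to 0.44), with 14 of 20 higher, among them the sodium transporter gene Slc9a3 (564 against 216 CPM) and the bile acid transporter gene Slc51b (62.6 against 29.6 CPM). Goblet cell genes had a median of 0.19 (-0.13 to 0.38), with 11 of 18 higher, led by Bcas1 (116 against 67.9 CPM). Both medians lay above 99% of the matched random lists, but the goblet median was 0.00 with thinned bins, -0.01 with medians over lesions and -0.30 in epithelium-rich bins.

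**Figure D3:**
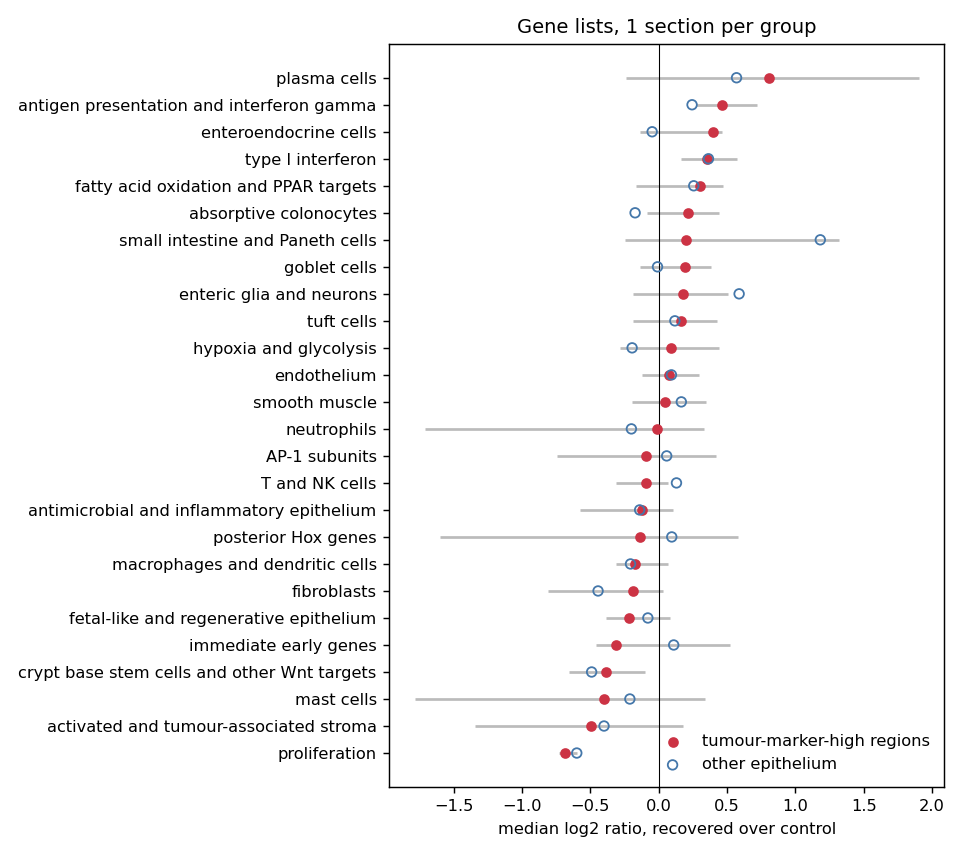
Median log2 ratio, recovered over control, of 26 fixed gene lists in tumour-marker-high regions (filled points, with the interval of the median over genes as a line) and in other epithelium (open points). The proliferation list stands at -0.69 in the tumour-marker-high regions and at -0.60 in other epithelium.

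Of the 12 named genes that were highest in the recovered tumour-marker-high regions, Zbtb16 came first, with 80.9 CPM (79.0 to 82.9) against 6.35 CPM (5.87 to 6.86), an 11.2-fold difference. This transcription factor gene (chromosome 9, 48651797 to 48836225) is a known glucocorticoid target. So are the kinase gene Sgk1 (913 against 217 CPM; chromosome 10, 21882184 to 21999903), the glucocorticoid receptor chaperone gene Fkbp5 (230.0 against 64.6 CPM; chromosome 17, 28398753 to 28486149) and the clock gene Per1 (247 against 74.1 CPM). The stress gene Depp1 (50.1 against 8.40 CPM), the lipocalin gene Apod (42.1 against 8.69 CPM) and the metallothionein gene Mt2 (1076 against 329 CPM) were also in this group. The growth factor protease gene Pappa (32.8 against 7.35 CPM) and the acute phase gene Serpina3n (68.2 against 16.3 CPM) followed. Antibody genes Igha (908 against 231 CPM) and Igkc (1088 against 289 CPM) and the class I gene H2-Q6 (109 against 32.0 CPM) completed it. The median over lesions was 54.9 against 31.6 CPM for H2-Q6 and 37.1 against 14.4 CPM for Serpina3n. H2-Q6 has near-identical neighbours in its family, so its value is uncertain.

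Of the 12 lowest genes, the collagenase gene Mmp13 (chromosome 9, 7272514 to 7283333) was lowest, with 2.73 CPM (2.39 to 3.11) in the recovered and 30.3 CPM (29.3 to 31.4) in the control regions, a log2 ratio of -3.07. Il1rl1, which encodes the receptor of interleukin 33 (chromosome 1, 40404864 to 40465418), had 19.95 CPM (19.0 to 20.9) against 141 CPM (138 to 143). Medians over lesions were closer, with 2.46 against 11.98 CPM for Mmp13 and 6.06 against 18.3 CPM for Il1rl1. The activin gene Inhba had 19.9 against 52.1 CPM. Epithelial genes were Lgals2 (17.3 against 85.9 CPM), the keratin gene Krt36 (17.5 against 62.4 CPM) and the gasdermin gene Gsdmc4 (52.4 against 149 CPM). The others were Tm4sf1 (28.8 against 72.1 CPM), Pcyox1l (29.98 against 105 CPM) and the chaperone gene Hsph1 (19.6 against 64.0 CPM), with the splicing kinase gene Srpk2 (31.6 against 87.7 CPM), Clec2e (13.6 against 35.5 CPM) and the creatine kinase gene Ckb (35.3 against 87.8 CPM). In epithelium-rich bins the log2 ratio was -1.88 for Mmp13, -1.64 in place of -2.76 for Il1rl1, -0.28 in place of -1.35 for Inhba and -0.67 in place of -1.30 for Tm4sf1. Among the higher genes it was 3.14 in place of 2.44 for Depp1 and 1.55 in place of 2.15 for Apod. Among all 24 named genes the widest Poisson half-interval was 13.3% of the value, for Mmp13 with 225 UMIs.

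**Figure D4:**
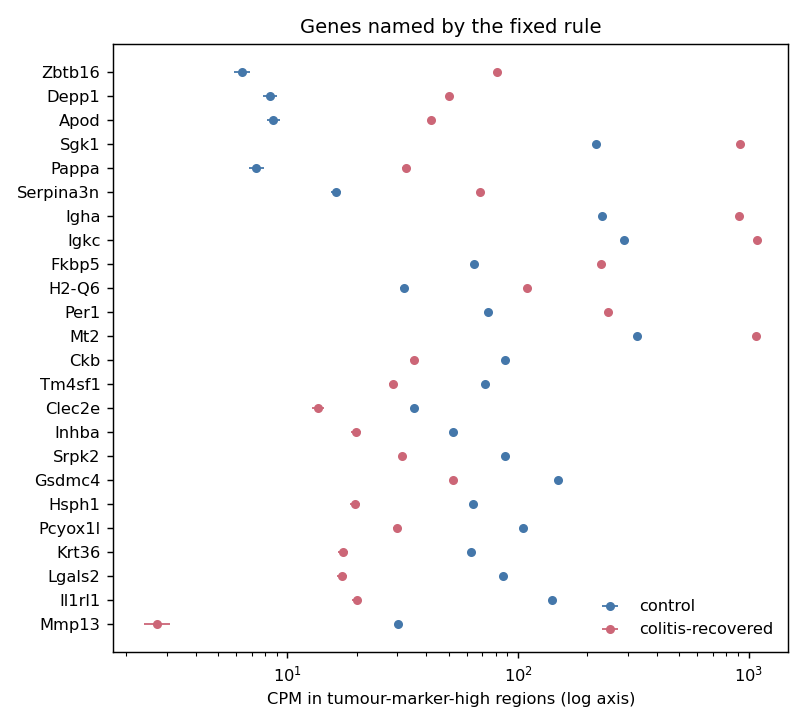
CPM of the 24 named genes in tumour-marker-high regions of each section on a log axis, with exact Poisson intervals. Zbtb16 has 80.9 CPM in the recovered and 6.35 CPM in the control section, and Mmp13 has 2.73 and 30.3 CPM.

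Cell type lists inside the tumour-marker-high regions went both ways. Gastric pit and gland mucous genes, a list written after the data were seen, had a median of -1.22 (interval over genes -3.19 to 0.80), with 7 of 11 lower. Plasma cell genes had a median of 0.81 (-0.24 to 1.91), with 6 of 9 higher, and their sum was 2098 CPM in the recovered against 586 CPM in the control regions. The lists of activated stroma (-0.50, -1.35 to 0.18, 10 of 16 lower) and fibroblasts (-0.19, -0.81 to 0.03, 8 of 12 lower) had medians below 0, but both intervals spanned 0. Summed fibroblast CPM per lesion had medians of 2104 in the recovered and 3752 in the control section. Col1a1 had 467 against 834 CPM, Ptgs2, which encodes a prostaglandin synthase, 2.51 against 21.9 CPM, and the collagen crosslinker gene Lox was higher (40.2 against 18.2 CPM). Mast cell genes had a median of -0.40 (-1.79 to 0.34), and the proteases Mcpt1 (92.6 against 322 CPM) and Mcpt2 (19.7 against 72.3 CPM) were lower. Summed mast cell CPM per lesion was nearly level, with medians of 86.2 and 90.5 CPM. The other medians were those of T and NK cells (-0.10), macrophages and dendritic cells (-0.17), neutrophils (-0.01), endothelium (0.08), smooth muscle (0.05), and enteric glia and neurons (0.18). The enteroendocrine list stood at 0.39, tuft cells at 0.16, B cells at 0.26 over 3 measurable genes, and red blood cells at 0.05 over 4.

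Of the remaining lists in these regions, antimicrobial and inflammatory epithelium stood at -0.12 with 13 of 20 lower, among them the antimicrobial lectin genes Reg3b (179 against 406 CPM) and Reg3g (51.8 against 135 CPM). Fatty acid oxidation and PPAR targets stood at 0.30, hypoxia and glycolysis at 0.09, posterior Hox genes at -0.14, and small intestine and Paneth cells at 0.20. The epithelium list stood at -0.06, so the epithelial share of these regions was near level between the sections by this measure.

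The third comparison asked whether these differences belonged to the lesions or were also present in the epithelium around them. The lower levels of proliferation and stem cell genes were found there too, as were the higher levels of Zbtb16, Mt2, Depp1 and Apod, and gastric-type mucus genes were far higher in the control section. Other epithelium made up 48.5% of recovered bins (48.2 to 48.8) and 52.7% of control bins (52.4 to 53.0). Proliferation genes had a median of -0.60, with 23 of 24 lower and Rrm2 higher (78.0 against 68.9 CPM), and the crypt base and Wnt list had a median of -0.49, with 15 of 19 lower. Gene by gene, the ratio in the tumour-marker-high regions minus that in other epithelium had a median of -0.09 for proliferation and 0.05 for the crypt base and Wnt list. These differences were not tested.

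In the surrounding epithelium AP-1 subunits had a median of 0.06 with 7 higher and 7 lower, and the fetal-like list had -0.08. The fetal-like gene Clu was far lower in the recovered section (17.4 against 117 CPM), and 48.3% of control Clu UMIs lay in the bins with high gastric-type genes. Antigen presentation stood at 0.24. Absorptive colonocyte genes were at -0.17, where the tumour-marker-high regions had 0.21, with lower Aqp8 (694 against 1346 CPM) and Car4 (588 against 1037 CPM). Goblet cell genes were at -0.01, with lower Clca1 (593 against 1406 CPM). Plasma cell genes were at 0.57, with Igha at 5839 against 2272 CPM. Fibroblast genes were at -0.44, enteric glia and neurons at 0.59, and small intestine genes at 1.18, where Apoa1 had 12.6 against 0.344 CPM. The Hoxb13-high zone held 17351 of 51050 control but 1526 of 47237 recovered bins of other epithelium. The 2 may thus differ in position along the colon. Without that zone or the gastric-gene-high zone, the medians were -0.49 to -0.40 for fibroblasts, 0.36 to 0.56 for enteric glia and neurons and 0.91 to 1.16 for small intestine genes. Single genes were not checked in this way.

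The 8 named genes that were highest in the recovered other epithelium were Zbtb16 (153 against 15.4 CPM), the metallothioneins Mt2 (2646 against 357 CPM) and Mt1 (7631 against 1528 CPM), Depp1 (99.96 against 13.0 CPM) and Apod (64.0 against 8.25 CPM). The antibody segment Igkv4-91 (36.0 against 5.95 CPM), the protease inhibitor gene Ctla2a (43.5 against 7.36 CPM) and the mitochondrial chaperone gene Trap1 (42.1 against 8.77 CPM) made up the rest. Antibody variable segments resemble each other, so Igkv4-91 is uncertain.

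All 8 lowest genes are known from the mucus-secreting and glandular stomach. Tff1 (chromosome 17, 31161395 to 31165060) had 1415 CPM in the control and 0.666 CPM in the recovered section, Tff2 1063 and 31.1 CPM, the pepsinogen gene Pgc 190 and 0.114 CPM, and Muc6 41.4 and 1.15 CPM. Gkn3 had 67.3 CPM in the control and 6 UMIs in the recovered section. For Gkn2 (1029 CPM in the control; chromosome 6, 87373365 to 87379494) the recovered section had 1 UMI. The log2 ratio was -10.00 with the pseudocount, and the counting interval of the ratio without it ran from -22.84 to -15.06. Gkn1 had 914 CPM in the control and 2 UMIs in the recovered section (-9.82, counting interval -19.41 to -14.51). Muc5ac had 52.2 CPM and 3 UMIs (-5.71, counting interval -13.93 to -10.10). In the control section 98.9% of Gkn1 UMIs and 98.7% of Tff1 UMIs lay in a zone of 3219 bins, 3.33% of the tissue. The zone was drawn by the level of the gastric mucous list, which holds both genes, so high shares follow in part from its definition. By the same threshold the recovered section had 272 such bins, 0.279% of its tissue.

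The whole sections do not depend on the region definition. However, tumour-marker-high regions and other epithelium hold most of their UMIs, so like values are no independent support. Over whole sections all 24 proliferation genes were lower (median -0.65), as were 17 of 19 crypt base and Wnt genes (-0.45). AP-1 subunits stood at 0.01, the fetal-like list at -0.17, antigen presentation at 0.25 and goblet cells at 0.01. Absorptive colonocytes were at -0.11, where the tumour-marker-high regions had 0.21. Enteric glia and neuron genes were higher in 11 of 12 cases (median 1.25), led by the neuropeptide gene Vip with 55.9 against 13.2 CPM. The distal colon gene Hoxb13 was lower, with a log2 ratio of -3.45, and the zone where it was high covered 23.9% of control and 2.21% of recovered bins. The sections may thus have held this part of the colon in unequal measure. However, the zone is drawn by Hoxb13 itself, and the posterior Hox list stood at 0.13 with 5 of 9 genes higher. Without that zone, the proliferation median in other epithelium was -0.45.

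The fourth comparison set tumour-marker-high regions against other epithelium within each section. The regions were richer in division and fetal-like genes in both animals and poorer in mature cell markers. All 24 proliferation genes were higher in both sections, with medians of 0.97 in the recovered and 1.12 in the control section. The fetal-like list had medians of 1.16 and 1.21, and AP-1 subunits 0.49 and 0.82. The crypt base and Wnt list had 1.35, with 13 of 19 higher and an interval over genes of -0.11 to 2.12, and 1.17, but regions chosen by Wnt targets favour such genes by construction. T and NK cell genes were higher by 0.60 and 0.84. Goblet cell genes had medians of -0.80 and -1.13. Of the absorptive colonocyte genes 18 of 20 and of the plasma cell genes 9 of 10 were lower in the regions, in both sections.

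Among the named genes highest in the regions in both sections were the retinol receptor gene Stra6 (584 against 8.05 CPM in the recovered and 637 against 6.46 CPM in the control section), the metallothionein gene Mt4 and the Paneth cell lysozyme gene Lyz1. The lectin gene Itln1 and the lipase-related gene Pnliprp1 followed. The log2 ratios of these 5 genes ran from 5.53 for Pnliprp1 to 6.01 for Stra6 in the recovered section and from 5.44 for Pnliprp1 to 6.42 for Stra6 in the control section. 1 more gene that the rule took is not reported here. The 6 lowest were the hormone genes Insl5 (-3.42 and -4.84) and Gcg (-3.39 and -4.07), the chloride transporter gene Slc26a3 (-3.25 and -4.01), Cyp4b1 (-3.25 and -3.24), and the antibody genes Igkv8-30 (-3.31 and -3.20) and Iglc1 (-3.20 and -5.06), recovered first.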

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

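Of the tests in this part, both on the gastric-type genes were chosen after the result was seen, and their list was written after it.

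Apart from the epithelium list, which defines the other epithelium, the medians of 3 gene lists lay on opposite sides of 0 in the 2 animals when tumour-marker-high regions were set against other epithelium within each section. None of these differences was tested. The gastric pit and gland mucous list had a median log2 ratio of -4.71 over 12 genes in the control section and 0.77 over 6 genes in the recovered section, a difference of 5.48. The list of gastric parietal, chief and endocrine cells had -0.11 over 3 genes and 0.73 over 2 genes, a difference of 0.84. The list of small intestine and Paneth cells had 0.19 in the control and -1.23 in the recovered section, a difference of -1.42, and its interval over genes spanned 0 in both sections.

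The gastric mucous genes of the control section lay mostly in a zone of 3219 bins chosen by their own level. There Tff1 reached 28886 CPM, Gkn2 20858 CPM and Muc5ac 1078 CPM. Acid-secreting stomach tissue carried over onto the section is a candidate explanation. Atp4a, Atp4b, Cblif and Pga5 together had 13.7 CPM in the zone (Poisson interval 11.7 to 15.9). This lay between the bounds of 100 CPM for such tissue and 10 CPM against it, so the explanation cannot be told apart. Pga5 alone had 8.48 CPM, Atp4a 3.95, Atp4b 1.15 and Cblif 0.082 CPM, near the lower bound. The pepsinogen gene Pgc had 11172 CPM, but it belongs to the gastric mucous list and so does not speak for acid-secreting tissue. A fragment with no colon epithelium would lack Cdx2, which stood at 194 CPM in the zone, 0.388 of its level in other epithelium (0.372 to 0.404), likewise between the bounds set. The window of the score could also have drawn neighbouring colon bins into the zone. The colon mucin Muc2 had 46124 CPM there and 41868 CPM in other epithelium of the control section, while Car1 had 1726 and 13807 CPM. These values go different ways and do not settle it. With 1 control animal no biological explanation was tested.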

How the results depend on the processing

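No paired analysis was possible because each group has 1 section. Over the alternatives for the main results, 172 values stayed within the interval of the reported value, 12 moved beyond it and 1 with an interval off 0 reversed. Values whose interval spans 0 also changed sign under some settings: the share, the lesion area, goblet cells and AP-1 subunits. For those added after seeing the data, 48 stayed and 1 moved. Among single genes and other lists 35 stayed and 53 moved, and under the added ones 149 stayed and 37 moved. These last counts overstate the change. Lists with too few genes for an interval were always counted as moved, even where the value was the same. Genes named within sections were judged by a fixed narrow margin in place of an interval. The proliferation median in tumour-marker-high regions ranged from -0.72 to -0.40 and the crypt base and Wnt median from -0.47 to -0.32, below 0 under all 18 alternatives each. AP-1 subunits ranged from -0.11 to 0.20 and the fetal-like list from -0.25 to -0.01.

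The log2 ratio of the tumour-marker-high share, 0.01 as reported, was 0.05 with a threshold 25% lower, -0.04 with one 25% higher, 0.05 with thinned bins, -0.59 with regions from joint clustering and -0.18 without the largest lesion of each section. The last follows from the size of 1 lesion, which held 24.1% of the recovered region. The ratio of median lesion areas, 0.55 as reported, ranged from -0.47 to 0.55, and thresholds, window, definition, clustering and thinning gave 0.01 to 0.14. Antigen presentation, 0.46 as reported, was 0.83 with joint clustering, 0.07 with thinned bins, 0.90 in epithelium-rich bins and reversed to -0.17 with medians over lesions. Epithelium-rich bins also gave -0.40 for proliferation and -0.30 for goblet cells. TMM factors lowered the proliferation median within sections to 0.87 in the control and 0.74 in the recovered section. Without the Hoxb13-high zone, proliferation in other epithelium was -0.45. Apart from the largest lesion, the cause was not tested. Depth limits genes with few UMIs: a sum of 100 UMIs is known to within 81.4% to 122%.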

Other observations

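In this part, the test on clock genes was chosen after the result was seen, as were the lists of glucocorticoid, clock, heat shock and cold-induced genes, the quadrant pairs and the Hoxb13-high zone.

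Genes that respond to glucocorticoid hormones were higher in the recovered section in each compartment. Of 19 listed genes, 15 were higher in tumour-marker-high regions (median log2 ratio 0.81), 18 in other epithelium (1.07) and 19 in the remaining bins (1.55). Besides those already named, Klf15 had 19.9 against 4.15 CPM and Tsc22d3, which encodes an anti-inflammatory leucine zipper, 68.2 against 25.5 CPM in the tumour-marker-high regions, while Lcn2 was lower there (8.97 against 17.3 CPM). The list includes genes that led the named ones, and 3 members are also in fixed lists, so its median is no independent evidence. Heat shock genes were lower in 13 of 13 cases in these regions (median -0.81), with Hspa5 at 116 against 255 CPM, and both cold-induced genes were higher, Cirbp at 242 against 84.8 CPM.

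In the remaining bins, largely muscle and connective tissue by their genes, type I interferon genes were higher in the recovered section (median 0.80, 16 of 17) and enteric glia and neuron genes were higher (1.34, 10 of 12). Antigen presentation genes were lower there (-0.36, 15 of 22), opposite to their summed value in tumour-marker-high regions. All 10 B cell genes (-1.45), all 13 macrophage and dendritic cell genes (-0.54) and 11 of 12 fibroblast genes (-1.11) were lower there. The remaining bins also differed in makeup: gastric mucous genes summed to 10902 CPM in the control and 7.22 CPM in the recovered section. How far this affects the other lists was not tested.

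The lower proliferation genes of the recovered tumour-marker-high regions were set against 3 technical explanations. Depth acting through which bins were called is argued against. With every bin thinned to 500 UMIs and the regions called again, the median was -0.61 (interval over genes -0.67 to -0.46). Random thinning leaves ratios of summed CPM nearly unchanged by design, so it could test no other effect of depth. Outside the Hoxb13-high zone the median was -0.66 (-0.70 to -0.58). That zone held 1513 of 27401 control and 131 of 27698 recovered tumour-marker-high bins. The bins of the zone thus do not account for the lower median. Whether distal colon lies outside the zone, which is drawn by Hoxb13 alone, cannot be told apart. Fewer epithelial cells in the recovered regions cannot be told apart, as the median in epithelium-rich bins was -0.40 (-0.50 to -0.30), at the bound set beforehand. The epithelium list was near level (-0.06, -0.19 to 0.09), but it does not count cells. Earlier colitis stays open, with a median of -0.63 over 16 pairs of quadrants of the whole sections (lowest pair -1.18, highest -0.06), because 1 animal per group cannot separate it from any other difference between 2 animals.

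The higher glucocorticoid-responsive genes were set against a different mix of cell types, which would leave medians near 0 within clusters of like bins. The lowest of 14 cluster medians was 0.71, above the bound of 0.5 set beforehand, but its interval over genes was wide (-0.07 to 1.43). That cluster was the only 1 that joint clustering took as tumour-marker-high. In 11 clusters the whole interval lay above 0.5, a count chosen after seeing the result. In those clusters this argues against cell mix as the sole cause, though bins of 1 cluster may still differ in makeup. For the tumour-marker-high cluster, cell mix cannot be told apart. Another time of day at collection cannot be told apart. Opposite signs of the clock genes of the Dbp and Per phase and of the Bmal1 phase would have favoured it. In whole sections their medians were 0.31 (-0.14 to 0.52) and 0.49 (0.12 to 0.99). In tumour-marker-high regions they were 0.58 (0.37 to 0.82) and 0.33 (0.23 to 1.34). In other epithelium they were 0.23 (-0.42 to 0.47) and 0.52 (0.03 to 1.26), and in the remaining bins -0.05 (-0.26 to 0.60) and 0.69 (0.27 to 1.85). Dbp itself was lower in whole sections (-0.80), where 8 of the 10 genes of its list were higher. Earlier colitis stays open as well, with a median of 1.07 over the 16 quadrant pairs of whole sections (lowest pair 0.87, highest 1.30) from 1 animal per group.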
